A study of Gallus gallus with 6 samples.

How the data were processed

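RNA was extracted from mesenchyme dissected from chick embryos and sequenced as polyA libraries, 1 library for each of presumptive forelimb HH15, forelimb HH19, hindlimb HH18, neck HH19, flank HH19 and a further library labelled flank and neck HH19. The authors deposited 1 table of 17781 genes. The reads columns of the deposited table are counts per gene. The normalised columns made by the authors are CPM (counts-per-million values), scaled to the reads counted to the genes of the table. Each is its reads column times 1 constant. The fold columns deposited by the authors are a ratio of the normalised values of 2 single libraries. The remaining columns deposited by the authors give a p-value for each pair of libraries, with neither the test nor an adjustment stated. The submitters' processing notes name TopHat 1.4.0 and the genome build galGal4 without giving their role; the read counter and the annotation are not stated. The table's coordinates do not match that build by name, so coordinates were left out. The column of the library labelled flank and neck was matched by its initials and stage (1 column), and 0 per-sample columns remained unused. The flank library's title and column give 9 where its source label gives HH19; it was taken as HH19, and its stage rests on that label.

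Genes are named by the symbol in the table where there is one (10291 genes). Otherwise a UniProt entry name (2392 genes, and 791 more whose entry name equals a RefSeq symbol), an Ensembl ID (2926), the symbol of a RefSeq protein accession (1234) or the table's description (133) was used. In 14 entries the name had become a spreadsheet date, and these stayed unnamed. Entries of UniProt form carry the suffix _CHICK, with HOX genes in the form HXD12_CHICK. The table lists ALDH1A2 as AL1A2_CHICK, BMP5 as P87373_CHICK, BMP7 as Q9I8T6_CHICK, CDH6 as CADH6_CHICK, CDX2 as P79788_CHICK, CHRDL1 as CRDL1_CHICK, COL12A1 as COCA1_CHICK, COL1A2 as CO1A2_CHICK, COL2A1 as CO2A1_CHICK, COL6A1 as CO6A1_CHICK, COL6A2 as CO6A2_CHICK, CRABP1 as RABP1_CHICK, CXCL12 as Q6T7C0_CHICK, CYCS as CYC_CHICK, DCX as Q98SS5_CHICK, DUSP6 as Q7T2L9_CHICK, ELAVL4 as Q9PW22_CHICK, FBN2 as Q9PUC7_CHICK, FGF10 as O42407_CHICK, FGF18 as Q9I950_CHICK, FSTL4 as Q71SY9_CHICK, GAP43 as NEUM_CHICK, HBAA as HBA_CHICK, HBZ as HBPI_CHICK, HSPE1 as O42283_CHICK, KLF6 as Q5ZI79_CHICK, KRT5 as Q6PVZ5_CHICK, LIN28A as LN28A_CHICK, LIN28B as LN28B_CHICK, NGFR as TNR16_CHICK, PAX7 as O42349_CHICK, POSTN as Q6DMS3_CHICK, SALL1 as Q9DF77_CHICK, SALL3 as Q90ZW5_CHICK, SHOX as Q00G66_CHICK, SPRY4 as A0FK60_CHICK, TBX18 as Q4TVR1_CHICK, TFAP2A as O13111_CHICK, TNC as TENA_CHICK, TRIM71 as LIN41_CHICK, TWIST2 as Q9YH69_CHICK. Entry FAS_CHICK was not taken for the gene FAS. COL1A2 and the entry Q700F0_CHICK are of the same locus and share reads.

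CPM were recomputed from the counts, which give the deposited values. Pairwise comparisons used log2(CPM + 1) and genes at 1 CPM or more in at least 1 library compared, and counted genes at least 2-fold apart; they have 1 library each and no test. For limb against non-limb, genes were counted when the 3 limb libraries did not overlap neck and flank and were at least 2-fold apart. The same classes were compared by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided, adjusted p below 0.05) on counts with TMM normalisation, where the spread is that between tissues and stages of a class; the common biological coefficient of variation was 0.283. The design made beforehand assumed FPKM values and limma, with edgeR if the table held counts, which it did. Leaving out the library labelled flank and neck from the classes was planned because its tissues overlap those of the other non-limb libraries. The authors' p-values were adjusted by Benjamini-Hochberg for a count of their own. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

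Gene lists (31 lists, 830 genes) were fixed beforehand from textbook knowledge, except the reprogramming factors, which the study chose. Each list's median difference was placed among 10000 random lists of the same size drawn from 20 bins of mean expression (seed 7). The list of ribosome assembly genes was added later and is not among the 31. Named genes are the 15 with a symbol and the largest gap between the classes higher in limb and the 10 lower, the 8 largest differences per direction in each pairwise comparison, all limb field and reprogramming genes, and up to 4 genes with the largest difference per other list; where a symbol had several entries, that with the highest mean was used. Genes outside this rule are said to have been named after their values were seen.

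Intervals are Wilson intervals at 95%, and the floor is 3 reads per library; both cover counting error only. Folds against 0 reads are lower bounds against that floor. Alternatives were another pseudocount (0.1), no filter or one at 5 CPM, thresholds of 1.5-fold and 4-fold or an adjusted p of 0.1, a common upper quartile, centring on the median, library totals, DESeq2 size factors, no trend in the prior variance, DESeq2, limma, each library left out (for the class counts, named genes and list medians), the library labelled flank and neck added or alone, blood genes or cell type lists left out, and the authors' p-values. A list median counted as kept when it moved by less than the distance from the middle to either end of its random lists' 95% range.

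The procedure was tested on simulated data with 200 changed genes. The edgeR test had a simulation of its own, separate from that of the counts by fold size and the lists (seed 11). edgeR called 13.4% of 67 genes changed 2-fold, 73.1% of 67 changed 4-fold and 83.3% of 66 changed 8-fold, with 5 false calls among 12166 genes. The edgeR simulation drew counts independently with the spread that edgeR had fitted to these libraries. It does not show how the test behaves where tissues share differences that the classes leave out. For the counts by fold size the simulated counts held counting error only, around a mean shared by all libraries. Every changed gene was 4-fold or 8-fold apart against a 2-fold threshold, so high recovery and few false calls followed from the setting. They do not show how these counts behave with variation between tissues or embryos. In that setting the no-overlap count recovered 100 of 100 genes at 4-fold and at 8-fold with 0 false calls among 12037. The pairwise counts recovered 99.0% of 4-fold genes for forelimb HH19 against HH15 and 100% in the other 2 comparisons, and all at 8-fold, with 11 false calls among 11691, 11 among 11803 and 8 among 11721. A raised list reached percentile 100, and 2 of 100 unchanged lists fell outside the 95% range. The unchanged lists were randomly chosen genes from the same simulated counts. They do not show how often lists of genes that vary together leave that range, so percentiles of the real lists are descriptions only.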

Results

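The series held 6 polyA RNA-seq libraries of chick (Gallus gallus) mesenchyme dissected directly from embryos, 1 library per tissue and Hamburger-Hamilton (HH) stage. The limb libraries were presumptive forelimb at HH15, forelimb at HH19 and hindlimb at HH18. The non-limb libraries were neck and flank at HH19, and a further library was labelled flank and neck at HH19. The deposited table gave reads for 17781 genes, with 7130877 reads counted in presumptive forelimb HH15, 7957948 in forelimb HH19, 9623046 in hindlimb HH18, 8139377 in neck, 8273762 in flank and 8925610 in the library labelled flank and neck. Between 11039 and 11623 genes reached 1 CPM (counts-per-million value) in a library, and 3 reads corresponded to between 0.312 and 0.421 CPM. Levels below are CPM, and differences between single libraries are on the log2(CPM + 1) scale. Intervals are 95% Wilson intervals. They and the 3-read floor cover counting error only, and with 1 library per tissue and stage no value has a replicate error. The gene with the most reads in each library, ENSGALG00000018384, took between 4.41% and 9.01% of them. The 4 globin genes measured took 3.26% of the reads in flank and between 0.004% and 0.368% in the other 5 libraries.

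The comparison of the 3 limb libraries with neck and flank asked which genes separated limb from non-limb mesenchyme whatever the limb type and stage. MYCN, a MYC-family transcription factor of growing progenitors, stood at 156, 139.7 and 142 CPM in forelimb HH15, forelimb HH19 and hindlimb HH18 and at 29.6 and 31.7 CPM in neck and flank. Its interval was 132 to 148 CPM in forelimb HH19, the lowest limb library, and 28.1 to 35.7 CPM in flank. NPM3, a nucleolar histone chaperone, stood at 743, 535 and 613 CPM in the limb libraries and 91.4 and 137 CPM in neck and flank. In the other direction, SVEP1, an extracellular matrix protein with roles in cell adhesion, stood at 6.45, 4.65 and 3.53 CPM in the limb libraries and 143 and 72.3 CPM in neck and flank. TNC (tenascin C), a matrix glycoprotein, stood at 1.12, 0.880 and 0.312 CPM in limb against 76.4 and 11.8 CPM in neck and flank. Of the 9 limb field genes measured, FGF10 alone had no overlap between the classes: TBX5, the transcription factor of forelimb initiation, was at 165 CPM in neck and 102 CPM in flank against 0.520 CPM in hindlimb.

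edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 17 of 12486 genes at an adjusted p below 0.05, 7 higher and 10 lower in limb. The spread was that between different tissues and stages of a class and not between replicates of one tissue. At an unadjusted edgeR p below 0.05 lay 2926 of the 12486 genes, and DESeq2 called 1336 of 11513 genes. Counts of list genes given below by either measure are to be read against these shares of all genes. MYCN rose by 2.38 ± 0.14 (log2, SE; edgeR adjusted p = 0.0199) and NPM3 by 2.58 ± 0.26 (edgeR adjusted p = 0.0445), each higher in 3 of 3 limb libraries. The others higher in limb included HSPE1, a mitochondrial chaperonin subunit, at 1.27 ± 0.13, EMG1, a methyltransferase of ribosome assembly, at 1.34 ± 0.14, and the stress-inducible gene ZFAND2A at 1.57 ± 0.16. Among the genes lower in limb, SVEP1 was at -4.32 ± 0.34 and C2orf40 at -2.35 ± 0.18 (edgeR adjusted p = 0.0299 for each), with TWIST2, a transcription factor of dermal and connective tissue fibroblasts, at -1.80 ± 0.15. COL1A2, a chain of type I collagen, was at -1.48 ± 0.14 and FBN2, a fibrillin of elastic microfibrils, at -1.89 ± 0.20. A second entry for the same locus, Q700F0_CHICK, was called beside COL1A2, so reads shared between these entries leave the level of each uncertain. TWIST2, COL1A2 and FBN2 were named after their values were seen. Several larger differences did not pass. SALL1, a zinc finger factor of limb bud and kidney, was at 2.91 ± 0.48 (edgeR adjusted p = 0.0588) and the secreted calcium-binding protein SMOC1 at 3.55 (edgeR adjusted p = 0.0632). TNC was at -5.68 ± 0.87 (edgeR adjusted p = 0.0561) and SFRP1, a secreted Wnt antagonist, at -1.79 ± 0.21 (edgeR adjusted p = 0.0554).

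Counted by size alone, 152 genes were at least 2-fold apart with no overlap between the classes, 21 higher and 131 lower in limb. Of the 12486 genes, 5352 (42.9%) did not overlap at any size of difference, where chance gives 10% per direction and 20% in either. Parting forelimb HH15, neck and flank from the later buds instead gave 237 genes at least 2-fold apart and 4438 (35.5%) at any size. The median of all genes was shifted by -0.14 log2 between the classes. With each library centred on that median the split was 31 higher and 100 lower. The edgeR and no-overlap counts both changed when a library was left out. The no-overlap count can then only rise, and all 152 genes stayed in it each time. The edgeR test then has fewer libraries to estimate the spread from. A fall of its count therefore does not show dependence on a particular library. Leaving out forelimb HH15 raised the edgeR count to 620. Leaving out forelimb HH19, hindlimb HH18, neck or flank took it to 0, with 2151, 2345, 1535 and 1971 genes at an unadjusted edgeR p below 0.05. Without forelimb HH15, neck or flank the no-overlap count was 538, 389 or 597. Adding the library labelled flank and neck to the non-limb class left 26 no-overlap genes and 0 edgeR calls (2207 at an unadjusted edgeR p below 0.05).

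**Figure D1:**
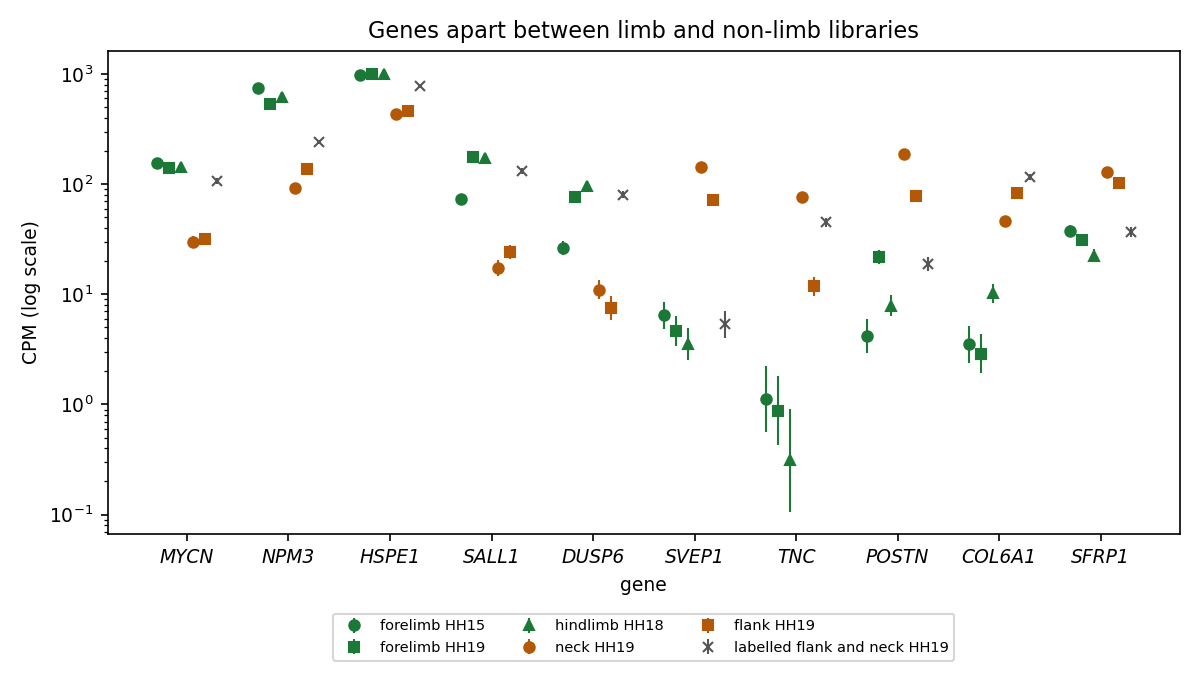
CPM on a log axis of 10 genes in each of the 6 libraries, as single points with 95% Wilson intervals for counting error only; crosses mark the library labelled flank and neck. SVEP1 is at or below 6.45 CPM in the 3 limb libraries and at or above 72.3 CPM in neck and flank, while MYCN is at or above 139.7 CPM in limb and at or below 31.7 CPM in neck and flank.

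Connective tissue matrix genes were lower in limb as a group. All 28 measured genes of the fibroblast matrix list had a lower mean in limb, with a median difference of -1.41 log2 (percentile 0.0 of 10000 random lists matched on expression, whose 95% range was -0.24 to 0.13). With any 1 library left out it lay between -1.84 and -1.06, below its random lists each time. Of the 28, 9 were at least 2-fold lower in limb without overlap and 19 were not. In all, 2 fell in the edgeR test over all genes, COL1A2 and FBN2, and 17 when adjusted over the list alone. COL6A1 and COL6A2, chains of type VI collagen, stood at 3.51, 2.89 and 10.2 and at 0.561, 1.01 and 3.33 CPM in the limb libraries, against 46.7 and 83.2 and 19.9 and 73.2 CPM in neck and flank. POSTN (periostin) was at 4.21, 21.7 and 7.90 CPM in limb and 186 and 77.4 CPM in neck and flank. The cartilage list was lower too, with a median of -1.15 over 11 genes, 5 of them lower when adjusted over the list alone and none over all genes (5 at an unadjusted edgeR p below 0.05, and DESeq2 called 5 and limma 0 over all genes). COL2A1, the fibrillar collagen of cartilage, was at 49.1, 23.7 and 23.5 CPM in limb and 138 and 63.8 CPM in neck and flank. In the library labelled flank and neck, 5 of the 9 matrix genes lay above the highest limb library.

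The transcription factors of the limb bud had a higher median in limb, with single genes in both directions. In the limb mesenchyme list 15 of 23 measured genes had a higher limb mean (median 0.54, percentile 100), and without neck the median was 0.07, within the range of its random lists. Adjusted over the list alone, SALL1, SALL3, TFAP2A, TBX15 and TFAP2C were higher and TWIST2, TBX2, MSX2 and MEIS1 lower; SALL3, TFAP2C, TBX2, MSX2 and MEIS1 were named after their values were seen. Over all genes edgeR called TWIST2 alone (6 higher and 5 lower at an unadjusted edgeR p below 0.05), while DESeq2 called 5 higher and 4 lower and limma 1 lower. TFAP2A, a regulator of ectoderm, neural crest and limb bud outgrowth, was at 1.54 CPM in forelimb HH15 but 81.8 and 100 CPM in the later buds, against 0 and 0.604 CPM in neck and flank. The HOX genes of groups 9 to 13, which pattern the posterior body and the limb axis, had the highest list median, 1.80, with 13 of 13 higher on average in limb, yet none passed the edgeR test, alone or over all genes (4 at an unadjusted edgeR p below 0.05, and DESeq2 called 3 and limma 0 over all genes). All 13 reached 1 CPM in hindlimb HH18, against 4 in forelimb HH15, 9 in forelimb HH19, 1 in neck and 7 in flank. Some therefore entered through limb libraries only, and for these the higher limb mean partly follows from the filter. HOXA9 was at 22.7 CPM in forelimb HH15 and 67.3 CPM in flank, and HOXA11 at 0.561 CPM in forelimb HH15 against 25.5 and 121 CPM in the later buds. The 13 measured genes of HOX groups 1 to 8 had a median of -0.14 (percentile 27.4), within the range of their random lists. It was -0.48 without forelimb HH15 and -0.63 without flank, below that range, and 0.32 without hindlimb HH18, above it. The 9 limb field genes had a median of 1.44 (percentile 100). With any 1 library left out the medians of HOX groups 9 to 13 and of the limb field lay between 1.52 and 3.22 and between 1.03 and 2.32. FGF10, the mesenchymal signal for outgrowth, at 6.31, 13.4 and 20.4 CPM in limb and 3.19 and 1.93 CPM in neck and flank, passed over the list alone and not over all genes (edgeR adjusted p = 0.0855).

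The 5 reprogramming factors of the study's own list, which is not independent evidence because the study chose it, probably on these libraries, had a median of 1.12 (percentile 100; 0.71 to 1.49 with any 1 library left out), all with a higher limb mean. TRIM71, LIN28B and ZBTB16 passed when adjusted over the list alone and none did over all genes (3 at an unadjusted edgeR p below 0.05, and DESeq2 called 1 and limma 0 over all genes). TRIM71, an RNA-binding regulator of early progenitors, was at 131, 107 and 159.9 CPM in limb and 81.1 and 78.1 CPM in neck and flank. LIN28A, which blocks let-7 maturation in early cells, was at 336 CPM in forelimb HH15 and at 35.8 and 85.2 CPM in the later buds, against 44.97 and 46.9 CPM in neck and flank, so forelimb HH19 lay under both non-limb libraries. PRDM16, a zinc finger transcriptional regulator, showed the reverse order in the limb, 13.6 CPM at HH15 and 124 and 123 CPM in the later buds, with 50.1 CPM in neck and 3.51 CPM in flank. The 10 measured genes of the progenitor list, which include MYCN and share TRIM71, LIN28A and LIN28B with the reprogramming factors, all had a higher limb mean (median 0.46, percentile 99.9).

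Gene lists of growth and metabolism had higher medians in limb, some of which depended on single libraries. Without forelimb HH19 or neck the ribosomal protein median (0.26 or 0.28) and the mitochondrial median (0.19 or 0.28) lay within the range of their random lists, as did the glycolysis and hypoxia median without neck (0.28). The ribosomal protein list had 57 of 59 genes with a higher limb mean (median 0.31, percentile 99.6), and 35 passed over the list alone against none over all genes (42 at an unadjusted edgeR p below 0.05, and DESeq2 called 29 and limma 0 over all genes). For mitochondrial respiration 32 of 37 were higher (median 0.26, percentile 99.0), and 8 passed over the list alone, among them CYCS (cytochrome c) at 0.93 ± 0.14 and the complex I subunit NDUFA5 at 0.92 ± 0.16; none passed over all genes (20 at an unadjusted edgeR p below 0.05, and DESeq2 called 9 and limma 0). The glycolysis and hypoxia list had a median of 0.29 over 19 genes (percentile 99.2), with 6 higher and 1 lower over the list alone and none over all genes (8 higher and 1 lower at an unadjusted edgeR p below 0.05, DESeq2 6 and 1, limma 0). LDHB, a lactate dehydrogenase subunit, was at 2221, 1627 and 1261 CPM in limb and 713 and 917 CPM in neck and flank. Cell cycle genes had a median of 0.12 over 35 genes (percentile 80.8), with none passing in either edgeR count (11 at an unadjusted edgeR p below 0.05, and DESeq2 called 7 and limma 0 over all genes).

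Among signalling pathways, the retinoic acid list was lower in limb (median -0.77 over 15 genes, percentile 0.0; -0.33 and within its random range without hindlimb HH18), with RARB, a retinoic acid receptor named after its values were seen, and CYP26B1, a retinoic acid-degrading enzyme, passing over the list alone. The FGF list had a median of 0.06 over 14 genes (percentile 95.9), and lay above its random range without forelimb HH19 (0.13) or neck (0.36). Over the list alone FGF10 passed, as did DUSP6, a feedback phosphatase of FGF signalling, at 26.2, 77.2 and 96.6 CPM in limb and 11.1 and 7.49 CPM in neck and flank. For the Wnt list (23 genes, median 0.14, percentile 99.6) SFRP1 and FZD1, a Wnt receptor, were lower over the list alone. The median was -0.05 when only genes at 5 CPM or more entered. It lay within its random range without forelimb HH15 (0.035), forelimb HH19 (0.05), neck (0.10) or flank (-0.12). For the Hedgehog list (12 genes, median -0.28, percentile 20.7) SHH was higher and the coreceptors GAS1 and CDON, the latter named after its values were seen, were lower over the list alone. SHH was at 0.982, 3.52 and 3.12 CPM in limb and 0.246 and 0.242 CPM, under the 3-read floor, in neck and flank. The BMP list had a median of -0.36 over 17 genes (percentile 4.2), below its random range without forelimb HH19 (-0.39), hindlimb HH18 (-0.48) or neck (-0.33). The Notch and ephrin list had a median of -0.11 over 20 (percentile 67.7), which became 0.02 after centring and -0.51, below its random range, without hindlimb HH18. The stress and immediate early list had a median of 0.17 (percentile 99.2), within its random range without forelimb HH19 (0.01), hindlimb HH18 (0.14) or neck (0.13). Of its 16 genes, 4 were higher and 2 lower over the list alone, the lower being JUN at -1.73 ± 0.32 and KLF6 at -1.29 ± 0.25. None of the 116 measured genes of these 7 lists passed the edgeR test over all genes. In all, 16 were higher and 21 lower at an unadjusted edgeR p below 0.05, DESeq2 called 10 higher and 11 lower, and limma 1 in each direction.

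Lists of the lateral plate and of other cell types differed between the classes too, for several lists depending on single libraries. The lateral plate and coelomic lining list was lower in limb (median -1.64 over 12 genes, percentile 0.0), and lay between -2.03 and -0.73, below its random lists, with any 1 library left out. Medians were also lower for blood (-0.82 over 12, percentile 0.0), endothelium (-0.67 over 20, percentile 0.0) and neural tube (-0.67 over 9, percentile 0.8). The blood median rested on flank, where the 4 globins summed to 32615 CPM against 1770.2 CPM in neck and between 621 and 3677 CPM in limb. It was -0.02 without flank, the endothelium median -0.19 without neck and the neural tube median -0.43 without forelimb HH15, each within its random range. Higher medians were found for the pharyngeal and cranial list (0.48 over 10, percentile 100) and the myogenic list (0.47 over 9, percentile 100). The former lay within its random range without forelimb HH19 (-0.04), hindlimb HH18 (0.20) or flank (-0.47), and the latter without forelimb HH19 (0.14) or flank (0.09). The medians of cardiac genes (-0.73 over 5), somite and sclerotome (-0.46 over 3), endoderm (-0.35 over 6), intermediate mesoderm (-0.10 over 8), ectoderm (-0.09 over 15) and neural crest (0.04 over 13) lay within the 95% range of their random lists. Those of intermediate mesoderm and ectoderm became 0.02 and 0.03 after centring. Outside that range lay cardiac genes without forelimb HH15 (-1.31) or flank (-1.275), endoderm without neck (-0.83), intermediate mesoderm without neck (0.495), and neural crest without forelimb HH15 (0.355), neck (0.54) or flank (0.43). Over the lists alone the edgeR calls were PECAM1, an endothelial adhesion molecule, at -1.40 ± 0.23, the apolipoprotein APOA1 at -5.94 ± 1.15, TCF21 at -3.98, SALL1, SHH, and, in the neural tube list, ELAVL4 higher with GAP43 and DCX lower. ELAVL4 was named after its values were seen. None of the 108 measured cell type markers passed the edgeR test over all genes. Of them, 7 were higher and 19 lower at an unadjusted edgeR p below 0.05, DESeq2 called 4 higher and 8 lower, and limma 0. Over all genes 2926 of 12486 lay at that p and DESeq2 called 1336 of 11513. The numbers of markers are near these shares and do not set the markers apart from other genes.

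**Figure D2:**
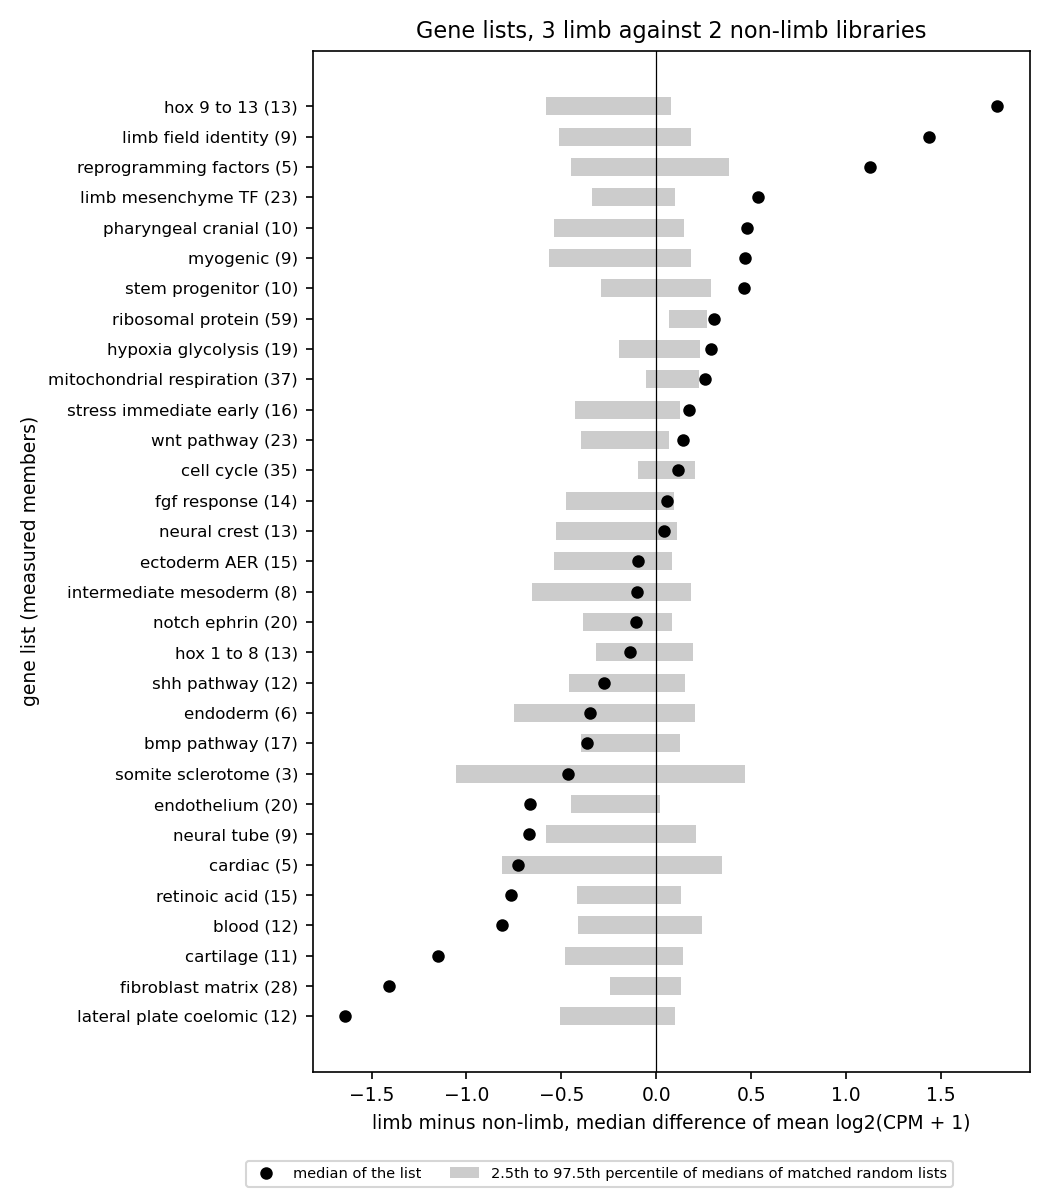
Points give the median limb minus non-limb difference of mean log2(CPM + 1) over the measured genes of each of the 31 gene lists, and grey bars the 95% range of medians of matched random lists. The median of HOX groups 9 to 13 is at 1.80 and that of the lateral plate and coelomic lining list at -1.64. The ectoderm, intermediate mesoderm and Notch and ephrin medians change sign after centring.

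The comparison of forelimb HH19 with presumptive forelimb HH15 asked what the established bud expressed that its field did not. LHX9, a LIM-homeodomain factor of distal limb outgrowth, stood at 0.841 CPM at HH15 and 95 CPM at HH19, and the posterior HOX gene HOXD12 at 0.561 CPM (interval 0.218 to 1.44) and 55.7 CPM (interval 50.7 to 61.1). TFAP2A went from 1.54 to 81.8 CPM, TBX15 from 0.421 to 22.5 CPM and the neuropeptide precursor NTS from 1.12 to 199 CPM. In the other direction ALDH1A2, the retinoic acid-synthesising enzyme of lateral plate mesoderm, was at 531 CPM at HH15 and 25.8 CPM at HH19, and GATA6, a lateral plate and heart factor, at 18.5 and 0.628 CPM. LIN28A was -3.19 log2 apart, at 336 CPM (interval 323 to 349.7) and 35.8 CPM (interval 31.9 to 40.2).

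Of 11807 genes, 1134 were at least 2-fold apart, 405 higher and 729 lower at HH19. With 1 library each the difference has no replicate check. The median of all genes was shifted by -0.10 log2, and after centring the split was 500 higher and 575 lower. Of the 9 measured HOX genes of groups 9 to 13, 7 were at least 2-fold higher, 1 lower and 1 neither (median 2.63, percentile 100), with HOXA11 at 4.09, HOXA10 at 3.62 and HOXD11 at 3.01 log2. In HOX groups 1 to 8, none of 13 was 2-fold higher and 3 were lower, among them HOXB1, at -2.11, and HOXB3. In the limb mesenchyme list 11 of 23 were higher and none lower (median 0.99, percentile 100), among them MECOM, a zinc finger factor, at 3.17. Of the 7 measured limb field genes, LHX9, LMX1B (2.67), the dorsal limb determinant, and LHX2 (1.80) were higher, while TBX5 was at -0.88, HAND2, a factor of posterior limb identity, at -0.96 and FGF10 at 0.98. The list's median of 0.98 became -0.19 when no filter on low values was used. Among the reprogramming factors PRDM16 (3.10) and ZBTB16 (2.04) were higher and LIN28A lower, with LIN28B at -0.60 and TRIM71 at -0.29.

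Single signalling genes differed between the stages as well. The BMP list (4 of 16 higher and 3 lower, percentile 71.6) and the FGF list (4 of 14 higher and 3 lower, percentile 43.8) had medians within the range of their random lists. The Hedgehog list had a median of 0.38 above it (percentile 99.7), with 2 of 11 genes higher and none lower. The BMP antagonists GREM1, also a target of Hedgehog signalling in the bud, and CHRDL1 were higher at HH19 by 3.45 and 3.26, and BAMBI and BMP5 were at -2.75 and -2.91. FGF18 and the FGF feedback inhibitor SPRY4 were at 2.32 and 2.17, and the receptors FGFR2 and FGFR3 at -2.13 and -1.99. Of the 22 measured Wnt genes 2 were higher and 6 lower (median -0.57, percentile 0.0), the lower including RSPO3 (-3.16) and WNT2B, a Wnt ligand of the forelimb field, at 29.03 CPM at HH15 and 0.880 CPM at HH19. Lists of cell types and tissues differed in the same comparison. Of 11 lateral plate and coelomic lining genes 8 were lower and 1 higher (median -1.70, percentile 0.0), with BNC1 at -3.12 and GATA5 at -3.02. That list holds lateral plate factors such as GATA6, so it does not mark only cells other than the sampled mesenchyme. Of 14 ectoderm genes 8 were lower and 2 higher (median -1.12, percentile 0.0), with KRT5 and KRT8, epithelial keratins, at -3.52 and -3.44. Cartilage genes were lower too, 5 of 10 with none higher (median -0.745, percentile 0.2). Of 28 matrix genes 7 were lower and 4 higher (median -0.43, percentile 0.0). Of 12 neural crest genes 7 were higher and 2 lower (median 1.14, percentile 100), and of 9 myogenic genes 5 were higher and 1 lower (median at percentile 100), with PAX3, a factor of migrating muscle precursors and neural crest, at 3.48. The myogenic median, above 0 here, became -0.29 without the filter. Also higher were blood genes, 4 of 9 with none lower (median 0.97, percentile 100; HBAD at 2.30 and HBZ at 1.78), pharyngeal and cranial genes, 5 of 7 with 1 lower (median 1.29, percentile 100), and intermediate mesoderm genes, 3 of 7 with 1 lower (median 0.91, percentile 100). Somite (1.46 over 3) and neural tube medians (0.35 over 6) lay above their random ranges and the cardiac median (-1.28 over 3) below. Leaving out all genes of the cell type lists gave 1086 genes at least 2-fold apart. With a pseudocount of 0.1 the count was 1802, and 714 among genes at 5 CPM or more. All 1134 genes also had a p-value in the authors' deposited table that was below 0.05 after Benjamini-Hochberg adjustment, as had 4592 genes of any size. With 1 library per group these p-values are no replicate check.

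The comparison of hindlimb HH18 with forelimb HH19 asked what parted the limb types, with a difference of 1 stage between them. PITX1 and TBX4, the hindlimb identity factors, stood at 196 CPM (interval 188 to 205) and 131 CPM (interval 124 to 138) in hindlimb and at 0.377 CPM (interval 0.128 to 1.11) and 0.251 CPM (interval 0.0689 to 0.916) in forelimb. TBX5 stood at 0.520 CPM (interval 0.222 to 1.22) in hindlimb and 182 CPM (interval 173 to 192) in forelimb. The HOXC genes were found in hindlimb. HOXC10 was at 66.1 CPM against 0.377 CPM, HOXC11 at 42.7 CPM and at least 113-fold higher, and HOXC12 at 20.2 CPM and at least 53.5-fold higher, both against 0 reads in forelimb with the floor at 3 reads per library. HOXA13, the distal-most HOXA gene, was at 32.6 and 0.126 CPM, and ISL1, a factor of hindlimb initiation, was at 13.6 CPM and at least 36.1-fold higher. The genes lowest in hindlimb after TBX5 were the cadherin CDH6 (-4.11 log2), the axon guidance factor SEMA5A (-3.65), FSTL4 (-3.42), NTS (-3.42) and NDRG1 (-3.04).

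Of 11444 genes, 460 were at least 2-fold apart, 204 higher and 256 lower in hindlimb. With 1 library each the difference has no replicate check. Of 13 HOX genes of groups 9 to 13, 11 were higher and none lower (median 1.85, percentile 100), while of the 13 in groups 1 to 8 none was higher and 4 were lower (median -0.83, percentile 0.0). Among the lower were HOXB8 (-1.92), HOXD3 (-1.29) and HOXD4 (-1.01). Other limb field genes were closer, with LMX1B at 0.33, LHX2 at -0.18 and LHX9 at -0.70. The reprogramming factors PRDM16 (-0.01), LIN28B (0.01), ZBTB16 (0.21) and TRIM71 (0.57) were within 2-fold, and LIN28A was higher in hindlimb (1.23). BMP7 was at 2.38 and CHRDL1 at 2.17. The retinoic acid-binding protein CRABP1 was at -2.63 and the retinol transporter STRA6 at -1.69, while ALDH1A2 was at 1.24. Of 37 mitochondrial respiration genes none was higher and 2 were lower, among them COX8A (median -0.30, percentile 0.0). Among markers of other cell types, of 8 myogenic genes 4 were lower and 1 higher (median -1.05, percentile 0.0), with PAX3 at -2.41 and PAX7 at -2.23, and of 12 neural crest genes 4 were lower and none higher (median -0.25, percentile 2.4). Medians were also lower for intermediate mesoderm (-0.79 over 7, percentile 0.0; 0.14 without the filter), pharyngeal and cranial (-0.775 over 8, percentile 0.0) and somite genes (-0.95 over 3, percentile 0.5), and higher for blood (0.56 over 9, percentile 100), where no gene was 2-fold apart. Leaving out the cell type lists gave 439 genes. With a pseudocount of 0.1 the count was 904, and 289 among genes at 5 CPM or more. All 460 also had a p-value in the authors' deposited table that was below 0.05 after Benjamini-Hochberg adjustment, as had 3651 genes of any size. Those p-values rest on 1 library per group and are no replicate check.

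The comparison of neck with flank asked how far the non-limb source tissues differed from each other. HOX genes differed by position. HOXD9 was at 80.1 CPM in flank and at least 217-fold lower in neck, where it had 0 reads, HOXB9 was at 104 and 0.491 CPM in flank and neck and HOXA9 at 67.3 and 0.123 CPM. PITX1 was at 46.8 CPM in flank (interval 42.3 to 51.7) and 0.737 CPM in neck (interval 0.338 to 1.61). Neck held more of several genes also found in the later limb buds: LHX9 was at 25.6 and 0.363 CPM in neck and flank, LHX2 at 28.5 and 1.69 CPM and PRDM16 at 50.1 and 3.51 CPM. APOA1 was at 566 CPM in neck and 41.2 CPM in flank, and GATA4, a heart and endoderm factor, at 19.4 and 0.725 CPM. The neurotrophin receptor NGFR was at 35.3 and 1.09 CPM and the chemokine CXCL12 at 10.9 and 0.121 CPM.

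Of 11970 genes, 885 were at least 2-fold apart, 616 higher and 269 lower in neck. With 1 library each the difference has no replicate check. The split moved with the scaling: the median of all genes was shifted by 0.14 log2, rescaling to a common upper quartile gave 503 higher and 319 lower, and centring gave 446 and 335. Of 7 HOX genes of groups 9 to 13, 6 were lower in neck and 1 neither (median -3.96, percentile 0.0), and in groups 1 to 8 HOXA7 (-2.98), HOXB7 (-2.47) and HOXB8 (-2.13) were lower with 2 of the 13 higher. Of 8 limb field genes 3 were higher (LHX9, LHX2 and LMX1B) and 3 lower (PITX1, TBX4 and HAND2), with a median of 0.60 (percentile 99.6). In the limb mesenchyme list 7 of 18 genes were higher and 2 lower (median 0.41, percentile 100). Endothelial genes were higher in neck, 9 of 20 with 1 lower (median 0.83, percentile 100), including the angiopoietin receptor TEK (2.54) and VWF (1.89). So were matrix genes, 8 of 28 with 2 lower (median 0.44, percentile 100), including TNC (2.59), COL12A1 (2.37) and elastin, ELN (2.06). Of 8 intermediate mesoderm genes 4 were higher and none lower (median 0.94, percentile 100). Of 9 neural crest genes 4 were higher and 3 lower (median 0.97, percentile 100; -0.11 without the filter), and of 8 pharyngeal and cranial genes 3 were higher and 2 lower (median 0.60, percentile 98.8). The cardiac median (1.135 over 4) lay above its random range, and that of ectoderm (-0.41 over 12) below. The FGF (0.51), Wnt (0.46), retinoic acid (0.47) and Hedgehog (0.40) medians lay above their random ranges. Blood genes were lower in neck, 8 of 12 with 1 higher (median -1.75, percentile 0.0): the globins HBAD, HBE, HBZ and HBAA were at -4.24, -4.21, -4.20 and -4.16. Leaving the blood genes out of the table and the totals gave 849 genes, 571 higher and 278 lower, and leaving out all cell type lists gave 838. With a pseudocount of 0.1 the count was 1425, and 588 among genes at 5 CPM or more. All 885 also had a p-value in the authors' deposited table that was below 0.05 after Benjamini-Hochberg adjustment, as had 4119 genes of any size. Here too the p-values rest on 1 library per group and are no replicate check.

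The library labelled flank and neck was compared with the neck and flank libraries to ask whether it held values between theirs. Some limb bud genes were far higher in it than in either, but the limb mesenchyme list as a whole was not: 8 of its 23 genes were at least 2-fold above both and 6 below both (median 0.07 from the mean of neck and flank, percentile 92.3). The limb field list lay above its random range, with 3 of 8 genes above both and none below both (median 0.49, percentile 99.0). So did the FGF list, with 5 of 15 above both and 1 below both (median 0.44, percentile 99.5). The reprogramming factors lay below theirs (median -0.69 over 5, percentile 1.5). HOXD12 was at 237 CPM (interval 227 to 247) against 0.369 and 0.483 CPM in neck and flank, and HOXA11 at 81.3 CPM against 0.369 and 1.09 CPM. LDHA, a lactate dehydrogenase of glycolysis, was at 514 CPM against 25.7 and 27.7 CPM, and VEGFA, the hypoxia-inducible angiogenic factor, at 71.0 CPM against 6.63 and 4.11 CPM. SVEP1, at 5.38 CPM, and LIN28A, at 1.12 CPM, were far below both, while COL6A1 at 116 CPM was above both.

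Over 12388 genes the library differed from the mean of neck and flank by a median of -0.13 log2 with an SD of 0.89 across genes. Of them 18.9% lay between neck and flank, and with 1 library each the difference has no replicate check. At least 2-fold outside both lay 1339 genes, 640 above and 699 below, and at least 4-fold outside 336. Of 10 HOX genes of groups 9 to 13, 6 were at least 2-fold above both neck and flank and none below both, while in groups 1 to 8 none of 13 was above both and 6 were below both. The median differences from the mean of neck and flank were 3.63 (percentile 100) and -1.25 (percentile 0.0). Of 19 glycolysis and hypoxia genes 11 were above both and none below both (median 1.30, percentile 100), and of 59 ribosomal protein genes 2 were above both and none below both (median 0.46, percentile 100). Lateral plate and coelomic lining genes were lower, 6 of 11 below both libraries and 2 above both (median -2.57, percentile 0.0). So were retinoic acid genes, 6 of 14 below both and 1 above both (median -1.29, percentile 0.0). The neural crest median was higher (1.65 over 13, percentile 100), and those of endoderm (-1.95 over 4, percentile 0.0), ectoderm (-0.74 over 13, percentile 0.2), blood (-0.77 over 12, percentile 0.1) and matrix genes (-0.54 over 28, percentile 0.0) were lower. Of the 21 genes at least 2-fold higher in limb without overlap, 6 were at or above the lowest limb library here, and of the 131 lower ones 61 were at or below the highest limb library.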

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

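The tests of a mixture, of the lateral plate and coelomic lining list, of the globin ratios, of displacement by globin reads, of other splits of the libraries and of correlations between libraries were chosen only after the result was seen. Of 169 genes at least 4-fold above both neck and flank in the library labelled flank and neck, 13 were in the limb field, limb mesenchyme, HOX groups 9 to 13 or reprogramming lists. They drew attention because each was so far above both in a library that the class comparison left out; members of these lists that were not above are not named here. MECOM was at 304 CPM there against 56.02 and 6.65 CPM in neck and flank, HOXD12 at 237 against 0.369 and 0.483 CPM, TFAP2A at 192 against 0 and 0.604 CPM, SALL1 at 132 against 17.2 and 24.2 CPM and TBX18 at 122 against 7.62 and 0 CPM. LHX9 was at 117 against 25.6 and 0.363 CPM, HOXA11 at 81.3 against 0.369 and 1.09 CPM, HOXA10 at 77.9 against 0 and 14.5 CPM, TBX15 at 60.2 against 0 and 0.121 CPM and SHOX at 43.4 against 0.123 and 0.363 CPM. HOXD11 was at 22.6 against 0 and 0.242 CPM, HOXD13 at 10.3 CPM against 0 reads in both, and TFAP2C at 10.3 against 0.614 and 0.242 CPM.

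In the library labelled flank and neck 336 genes lay at least 4-fold outside both neck and flank. The tables argue against a mixture of the tissue in those libraries, which would lie between its parts, since 149 genes differed 4-fold between neck and flank themselves, and against the scaling of the libraries, since 344 genes lay 4-fold outside after centring. Limb tissue in the library, a wrong label, cannot be told apart from the label as given, since of 538 genes at least 2-fold apart between the later buds and both neck and flank, 72.9% lay nearer the bud mean (76 of 110 higher in buds, 316 of 428 lower), a share between the bounds set beforehand. Across 12737 genes, which are not independent replicates, this library correlated more closely with forelimb HH19 and hindlimb HH18 (Pearson 0.946 and 0.942, Spearman 0.942 and 0.939) than with neck and flank (Pearson 0.917 and 0.909, Spearman 0.915 and 0.907). TBX4 and PITX1 were at 0.112 CPM each. Forelimb HH19 also held them at or under the 3-read floor, so their levels do not tell against forelimb tissue. PITX1 was near the floor in neck too but far above it in flank, so its level here is unlike that of the flank library. A single gene does not settle which tissue the library labelled flank and neck holds. Of the 12737 genes, 78 were 4-fold above all 5 other libraries. A different part of neck and flank in this dissection is the biological explanation that the labels allow, and it stays open as untested.

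Forelimb HH15 parted from the later limb buds together with neck and flank: edgeR called 98 genes for the split of forelimb HH15, neck and flank against forelimb HH19 and hindlimb HH18, against 17 for limb against non-limb. The tables argue against the scaling of the libraries, since the lowest count over library totals, DESeq2 size factors and centring was 97. Cells of the coelomic lining in those 3 libraries may contribute. The median of the 12 measured genes of the lateral plate and coelomic lining list was 1.90 log2 higher in them (random lists -0.10 to 0.48). Of the 12, 8 were higher there by at least 1 and 2 were lower by at least 1. Among the higher, GATA5 was at 83.7, 222 and 224 CPM there and 9.42 and 31.4 CPM in the buds, BNC1 at 66.9, 43.4 and 106 and 6.79 and 2.81 CPM, and BNC2 at 60.4, 57.1 and 102 and 10.1 and 11.8 CPM. The list also holds lateral plate factors such as GATA6, so it cannot tell lining cells from lateral plate mesoderm itself. The buds also held 6 and 9 of the 12 genes at 1 CPM or more, 5 of the 12 are in another list, and no sort that would remove such cells is stated. The difference was not particular to this list. Higher medians were also found for the matrix, endoderm, cartilage and ectoderm lists (1.27, 0.97, 0.85 and 0.80). Those of the retinoic acid list and HOX groups 1 to 8 were 0.72 and 0.67. Other lists were lower there, among them HOX groups 9 to 13 (-2.61) and the limb field (-1.97). The stage of the forelimb stays open as untested, and so does the tissue of neck and flank.

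The 4 globin genes were far higher in flank than in neck, with HBZ at 14052 against 762 CPM, HBAA at 6675 against 373 CPM, HBE at 6666 against 360.5 CPM and HBAD at 5223 against 275 CPM. Displacement of other genes by globin reads is argued against as the cause of the larger number of genes higher in neck: without the blood genes 67.3% of the genes 2-fold apart were higher in neck, against 69.6% with them. Red blood cells in the dissected flank are a candidate source, since the log2 differences of the 4 genes lay between -4.24 and -4.16, a range of 0.09, as 1 source would give. Of the 12 measured blood genes, between 8 and 12 reached 1 CPM in each library, 1 is in another list, and no sort that would remove red cells is stated. A difference in the blood supply of flank and neck stays open as untested.

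For the 17 genes that edgeR called between limb and non-limb, 2 of the 10 splits of the 5 libraries into 3 and 2 gave as many genes, the real one included, and the highest other split called 98. The 10 splits are too few for a share under 0.05. The split that called several times more, with forelimb HH15 beside neck and flank, points to a structure of the samples.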

How the results depend on the processing

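The alternatives with DESeq2 and its size factors, limma on log2(CPM + 1), library totals, blood genes left out, cell type lists left out, the authors' p-values and every alternative for the library labelled flank and neck compared with neck and flank, and list medians with a library left out, were chosen only after the data were seen; the others were set before the data were examined. The authors' deposited q below 0.05 was planned and not run, because the table gives a p and no q. No paired analysis was possible because each tissue and stage has 1 library. For genes named in the limb against non-limb comparison, 396 of 487 values over 41 genes kept their direction and their side of the threshold, 50 passed where they had not, 34 no longer passed and 7 reversed. With a library left out, 141 of 204 kept both, 23 passed newly and 40 no longer passed. In the pairwise comparisons 837 of 883 gene values stayed within their counting interval and 46 moved, with no reversal among genes at least 2-fold apart. Of 916 list medians 801 stayed, 109 moved and 6 that had lain outside their random range reversed; sign changes within that range, as for the ectoderm, intermediate mesoderm and Notch and ephrin medians of the class comparison after centring (0.03, 0.02 and 0.02), are not counted as reversals. With a library left out, 118 of 155 class list medians stayed, 34 moved and 3 reversed (pharyngeal and cranial between -0.47 and 0.996, Wnt between -0.12 and 0.25). Of 31 lists, 5 without forelimb HH15, 8 without forelimb HH19, 6 without hindlimb HH18, 12 without neck and 7 without flank crossed a bound of their random range. The cause was not tested for any value below, except where the alternative itself sets a looser or stricter threshold or filter.

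The no-overlap count of 152 became 341 with a pseudocount of 0.1, 613 at 1.5-fold, 14 at 4-fold, 26 with the library labelled flank and neck added and 846 with it alone as the non-limb class, and between 184 and 597 with 1 library left out. With a library left out this count can only rise. It stayed within 1.5 times with genes at 5 CPM or more (134), a common upper quartile (139), centring (131) and blood genes left out (159). With no filter it was 152 again, which followed from the setting. A 2-fold difference on the log2(CPM + 1) scale needs at least 1 CPM in some library. The edgeR count of 17 became 259 with no filter, 30 with library totals, 914 at an adjusted p below 0.1, 93 with the library labelled flank and neck alone, and 0 with that library added (2207 genes at an unadjusted edgeR p below 0.05) or with no trend in the prior variance (2716). It was 15 at 5 CPM or more, 16 at a common upper quartile, 14 after centring and 13 with DESeq2 size factors. The main edgeR fit had 2926 genes at an unadjusted p below 0.05. Other tools called 1336 (DESeq2), 43 (limma on log2(CPM + 1)) and 26 (limma on log2(CPM + 0.1)). With 1 library left out edgeR called between 0 and 620. Without forelimb HH19, hindlimb HH18, neck or flank it called 0 at the adjusted threshold and 2151, 2345, 1535 and 1971 at an unadjusted p below 0.05. Without neck or flank, and with the library labelled flank and neck alone, the lone non-limb library is assumed to vary like the limb libraries. At a pseudocount of 0.1, 5 CPM or more, 1.5-fold, 4-fold and by the authors' p-values alone, the counts were 1802, 714, 2765, 219 and 4592 for forelimb HH19 against HH15 (1134), 904, 289, 1604, 66 and 3651 for hindlimb against forelimb (460), and 1425, 588, 2257, 149 and 4119 for neck against flank (885). Genes at least 2-fold outside neck and flank in the library labelled flank and neck (1339) numbered 336 at 4-fold.

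With the library labelled flank and neck alone as the non-limb class the class difference reversed for DUSP6 (-0.24), APOA1 (2.67), C2orf40 (0.44), TFAP2A (-1.62) and TBX15 (-2.09), and with it added for TFAP2A (-0.042) and TBX15 (-0.51). The Wnt median of the class comparison reversed at 5 CPM or more (-0.05). With no filter the medians reversed for limb field (-0.19) and myogenic genes (-0.29) in forelimb HH19 against HH15, intermediate mesoderm in hindlimb against forelimb (0.14) and neural crest in neck against flank (-0.11); at 5 CPM or more that of intermediate mesoderm reversed in the library labelled flank and neck (0.53). Depth limits genes near the floor of 3 reads, between 0.312 and 0.421 CPM, where 0 reads do not show absence.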

Other observations

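The genes of the paragraph that follows were chosen only after their values were seen, and the ribosome assembly test was set before its result was seen. EVX1, a homeobox factor of the posterior body, was at 17.3 CPM in hindlimb HH18 and 17.8 CPM in flank, against 1.96, 0 and 0 CPM in forelimb HH15, forelimb HH19 and neck, and CDX2, a regulator of posterior HOX genes, was at 12.3 CPM in forelimb HH15 and 5.92 CPM in flank. ABCC9, a subunit of potassium channels, was at 164 CPM in flank and 58.2 CPM in forelimb HH15 against 2.51, 3.84 and 4.55 CPM in forelimb HH19, hindlimb HH18 and neck. The scavenger receptor gene SCARB1 was at 55.1 CPM in forelimb HH15 and at or below 2.42 CPM in the later buds, neck and flank, and the carbonic anhydrase gene CA13 was at 117 CPM in flank and at or below 7.27 CPM elsewhere. LIX1 was at 116 CPM in hindlimb HH18 and 99.9 CPM in neck against 4.63, 6.28 and 8.58 CPM in forelimb HH15, forelimb HH19 and flank. The desmosomal gene DSP followed the grouping of forelimb HH15 with neck and flank, at 279, 167 and 423 CPM there and 28.1 and 41.4 CPM in forelimb HH19 and hindlimb HH18. SOX9, a factor of cartilage formation, was at 40.2 CPM in the library labelled flank and neck and at or below 6.41 CPM in the other 5.

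EMG1 and NPM3, both tied to the nucleolus, were among the genes higher in limb, and a hypothesis was that genes of ribosome assembly may be higher in limb as a group. The hypothesis came from the same libraries, and genes of ribosome assembly may vary together, so the list is no independent test of it. A list of 87 genes of ribosome assembly was written without the genes already seen, and 58 were measured. Of these, 57 had a higher limb mean and 53 were higher without overlap and none lower; the median was 0.55 log2, percentile 100 of matched random lists (95% range -0.10 to 0.13). edgeR called 0 of them over all genes, with 54 at an unadjusted p below 0.05, all higher in limb, while DESeq2 called 45 and limma 0. The class median of this list was not recomputed with a library left out. In the other comparisons the list's median lay within the range of its random lists. Percentiles were 38.4 for forelimb HH19 against HH15, 29.2 for hindlimb against forelimb and 6.2 for neck against flank. UTP3, NOP16, PNO1 and NHP2 were the list genes with the largest class differences, at 1.17, 1.05, 0.89 and 0.86 log2. All 58 genes reached 1 CPM in all 6 libraries, so cells of any type could carry the difference, and which cells do was not tested.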
